A study of Mus musculus with 2 samples.

How the data were processed

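Nuclear RNA was profiled by droplet-based 3' sequencing (10x Genomics) in livers of 12-week-old mice 48 h after partial hepatectomy, with 1 HKO and 1 WT library. The group of each library was taken from its sample title, since the genotype field held the age, and the HKO abbreviation is not spelt out in the labels. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized. Cell Ranger 5.0.0 is named per the file headers and in the submitters' processing notes, which also name STAR, Seurat 3.2.0 and GRCm38 with no role or order. The extract protocol in the labels describes total RNA purification, although the molecule is given as nuclear RNA, so how the nuclei were isolated is not given in the sources used here. Of 27998 genes in the deposited tables, 27645 matched the annotation (GENCODE vM21, GRCm38) by identifier, and coordinates come from that annotation.

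Barcodes with at least 500 genes and under 10% mitochondrial UMIs were kept, 14901 of 14912 in HKO and 14515 of 14701 in WT. The gene minimum removed none and the mitochondrial limit removed 10 in HKO and 186 in WT. Scrublet, run per library in scanpy 1.11.5 with an expected doublet rate of 0.1, marked 1 barcode in HKO and 0 in WT, so doublets were in effect not removed here. Whether the caller failed or doublets had been removed before deposit was not tested. Both libraries were clustered together without batch correction, on 2000 variable genes, 30 principal components and 15 neighbours, with shared-neighbour weights and the Leiden algorithm (leidenalg 0.10.2, igraph 0.11.9, resolution 0.5, scikit-learn 1.9.0). Clusters were named by marker genes fixed before the data were examined, as were the gene lists, the rule for named genes, the floors and most alternatives. A cluster needed at least 3 markers above the other classes, and among its 10 leading genes no other class could have more markers than its own. The requirement that a marker reach 20 CPM in some cluster, and that a class have at least 0.5 of its markers detected, was set after the data were seen. At resolution 0.5 no cluster could therefore take the name of the neutrophil (3 of 10 markers), erythroid (4 of 9) or mesothelial (1 of 8) class, while their markers still counted against other names. The cluster left unnamed, with hepatocyte markers but haemoglobin genes leading, held 0.0470% of HKO and 13.8% of WT nuclei.

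Raw counts were summed per library and class and scaled to the class total (CPM, counts scaled to a class total of 1e6). Hepatocyte-like nuclei held 38107034 UMIs in HKO and 42818400 in WT. Ratios are log2 of HKO over WT CPM after adding 0.5, for genes with a mean of at least 10 CPM, and folds are ratios of CPM. With 1 library per group no test was made and no p-value is given. Sums carry exact Poisson intervals, folds exact conditional intervals and shares exact Clopper-Pearson intervals, all at 95% and for counting error only. Each list's median ratio was set against 10000 random lists of the same size, drawn from 20 strata of mean expression, where at least 5 members were measured, which left 23 of 25 lists. The percentiles describe these 2 libraries only. Shares of nuclei with cell cycle transcripts were taken after thinning each nucleus to 2000 UMIs. In other classes with at least 100 nuclei per library, genes with a mean of at least 50 CPM were compared, leaving out genes higher in hepatocyte-like nuclei.

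Named genes were the 12 highest and 12 lowest ratios in hepatocyte-like nuclei, leaving out unnamed gene models and mitochondrial, Xist and Y-linked genes, up to 4 members of each list with the largest ratio in size, Sox9, and in each other class the 5 highest and 5 lowest ratios and up to 4 members of its list. The rule gave 110 genes in hepatocyte-like nuclei, and some genes it gave are not reported here. Quality facts use mitochondrial transcripts, nuclear retained RNAs, Malat1 and haemoglobin genes. The 4 haemoglobin genes summed to 36.3 CPM in HKO and 2.38 CPM in WT hepatocyte-like nuclei and 123 CPM in the WT nuclei of the unnamed cluster.

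The calculation was tested on simulated counts drawn at the depths of the hepatocyte-like sums over 8413 genes. All 50 genes at each of a log2 change of -2.00, -1.50, 1.50 and 2.00 were recovered past the size of 1 (100% each), 0% of 8201 unchanged genes were called, and 0 of 40 unchanged lists lay outside the central 95%. The simulated counts carried Poisson counting error only, with no variation between animals or libraries and no free RNA. They check the calculation and give no rate of false calls between livers. Alternatives covered the gene minimum, doublet removal, clustering resolution, scaling (median ratio size factors and TMM in edgeR 4.0.16 under R 4.3.3), equal weights per nucleus, thinning, expression floors and the rule for cell cycle shares. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.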

Results

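Single-nucleus RNA sequencing was done on livers of 12-week-old C57BL/6 mice 48 h after partial hepatectomy (PHx), the surgical removal of part of the liver, after which the remaining tissue regrows. The series compared mice named Sox9f/f, whose Sox9 gene carries loxP sites, with mice named Sox9HKO. There was 1 library per group, called WT and HKO in the sample titles, so no difference below has a replicate check and no test was possible. The HKO library held 14912 barcodes and 61123904 UMIs, with a median of 3286 UMIs and 1873 genes per barcode. The WT library held 14701 barcodes and 64609301 UMIs, with a median of 3430 UMIs and 1793 genes. The lowest barcode had 1181 UMIs in HKO and 1968 in WT. Both libraries carried Y-linked transcripts, with Uty at 309 CPM in HKO and 227 CPM in WT, and almost no Xist, at 0.393 and 0.142 CPM. Intervals in parentheses are exact 95% intervals of the counts and cover counting error only.

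Sox9 encodes a transcription factor of the bile duct lineage that also appears in hepatocytes near the portal tract and after injury. In hepatocyte-like nuclei it was at 5.77 CPM (5.04 to 6.59, 220 UMIs) in HKO and 11.3 CPM (10.3 to 12.3, 483 UMIs) in WT, a fold of 0.512 (0.434 to 0.601) for HKO over WT. At least 1 Sox9 UMI was found in 2.47% of 8680 HKO and 4.73% of 9437 WT hepatocyte-like nuclei, whose median depths were 3909.5 and 3812 UMIs. In endothelial-like nuclei, which should lack Sox9, the shares were 2.08% and 3.49% at median depths of 2067 and 3268 UMIs, and the levels were 5.82 CPM (4.33 to 7.65) and 8.28 CPM (5.99 to 11.1). The HKO hepatocyte-like level was thus no higher than the endothelial-like one, and the WT level was above the endothelial-like value with overlapping intervals. Endothelial-like nuclei also held hepatocyte RNA, with hepatocyte markers at 85.5% of their hepatocyte-like level in HKO and 95.1% in WT. The comparison therefore cannot tell whether hepatocytes of either library held Sox9 transcripts. Macrophage-like nuclei gave 5.91 CPM in HKO and 8.98 CPM in WT, and stellate-like nuclei 5.23 and 9.08 CPM. Cholangiocyte-like nuclei held 5 Sox9 UMIs in HKO (16.0 CPM, 5.19 to 37.3) and 2 in WT (19.7 CPM, 2.39 to 71.2), too few to order. Over all nuclei kept, the fold was 0.543 (0.476 to 0.619). The gene (ENSMUSG00000000567) lies on the plus strand of chromosome 11, 112782224 to 112787760, in GRCm38, with 3 exons and a 3' UTR from 112785508 to 112787760. The labels do not say which part is deleted, so a 3' tag in that UTR may lie outside it and then checks nothing.

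Nuclei were grouped by their transcripts to ask which cell classes the regrowing livers contained. Hepatocyte-like nuclei made up 58.3% (57.5 to 59.0) of the 14901 HKO nuclei kept and 65.0% (64.2 to 65.8) of the 14515 WT nuclei. Endothelial-like nuclei made up 15.8% in HKO and 7.71% in WT, macrophage-like nuclei 11.9% and 7.28%, and stellate-like nuclei 7.76% and 4.42%. Smaller classes were dendritic-like, with 357 HKO and 67 WT nuclei, T/NK-like, with 286 and 121, B-like, with 160 and 42, and cholangiocyte-like, with 122 and 30. A cluster led by haemoglobin and mitochondrial genes stayed unnamed and held 7 HKO nuclei (0.0470%) and 2001 WT nuclei (13.8%). The UMI floor of the libraries differed, with 3856 HKO and 288 WT barcodes under 2000 UMIs, and among nuclei of at least 2000 UMIs the order of the hepatocyte-like shares turned, to 69.6% (68.7 to 70.4) in HKO and 65.6% (64.9 to 66.4) in WT. At a clustering resolution of 1 a cluster of 3215 HKO nuclei led by haemoglobin genes was also left unnamed, and the HKO share was 36.6%. The main setting thus left haemoglobin-led nuclei out of the hepatocyte-like class in WT but hardly any in HKO. Neither the size nor the order of these shares is therefore read as a difference between the livers.

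**Figure D1:**
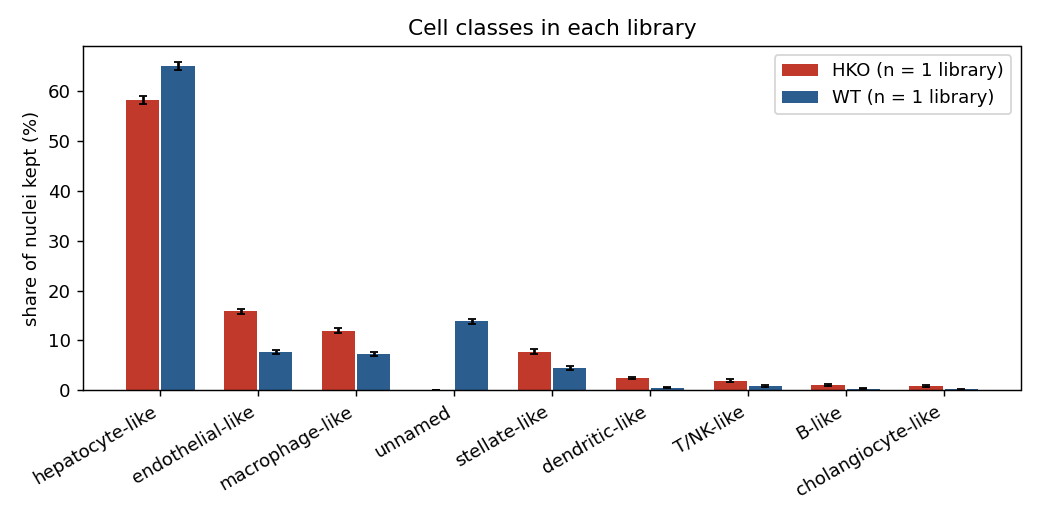
Share of nuclei kept (percent, y axis) in each cell class (x axis) for the HKO and WT libraries, 1 library each, with exact binomial 95% intervals as bars. Hepatocyte-like nuclei stood at 58.3% in HKO and 65.0% in WT, and the unnamed cluster at 0.0470% and 13.8%.

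Almost every large cluster belonged to 1 library, and such a cluster may reflect the library rather than a cell type. The hepatocyte-like class consisted almost only of clusters 0, 10 and 12 in HKO and clusters 1, 2 and 9 in WT, with cycling genes leading clusters 9 and 12. Endothelial-like nuclei were in cluster 3 in HKO and cluster 7 in WT, macrophage-like nuclei in clusters 5 and 8, stellate-like nuclei mostly in clusters 6 and 11, and T/NK-like nuclei in clusters 14 and 18. Hepatocyte transcripts were present in every class. The 15 hepatocyte markers had a median level in endothelial-like nuclei of 85.5% of the hepatocyte-like level in HKO and 95.1% in WT, whereas the endothelial markers in hepatocyte-like nuclei were at 4.47% and 5.50% of their endothelial-like level. Hepatocyte-like nuclei held a median of 52 hepatocyte marker UMIs in HKO and 97 in WT, and endothelial-like nuclei 23 and 86. Values for hepatocyte genes therefore describe the hepatocyte RNA of each library, in nuclei and free, and not nuclei alone. Clusters 0, 1, 9 and 12 had 6 to 14 hepatocyte markers above the other classes but 0 among their 10 leading genes. Whether some hepatocyte-like barcodes held free RNA and no nucleus was not tested. RNA composition also differed between the libraries. The median mitochondrial share of hepatocyte-like nuclei was 0.0745% in HKO and 0.265% in WT, Malat1, a nuclear RNA, was at 50687 CPM in HKO and 38063 CPM in WT, the list of nuclear retained RNAs that holds it was at 6.92% and 7.27% of UMIs, and Alb, the albumin gene, was at 2544 and 6049 CPM (Alb was chosen after its values were seen).

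The main comparison asked which hepatocyte transcripts differed between the HKO and WT livers during regrowth. The genes with the highest ratios in HKO included Cux2, a homeobox factor typical of female mouse liver, Lepr, the leptin receptor, and Lpin1, a phosphatidate phosphatase of triglyceride synthesis. Cux2 was at 93.6 CPM (90.6 to 96.7) in HKO and 2.83 CPM (2.34 to 3.38) in WT, a fold of 33.1. Lepr was 23.2-fold higher (18.4 to 29.8), at 39.6 against 1.70 CPM, and Lpin1 15.2-fold higher (14.5 to 16.1), at 571 against 37.4 CPM. The genes with the lowest ratios included the interferon-inducible GTPase genes Gbp6, Iigp1 and Igtp, the chemokine gene Cxcl10 and the immune checkpoint ligand gene Cd274. Iigp1 was at 115 CPM (112 to 119) in HKO and 1889 CPM (1876 to 1902) in WT, 16.4-fold lower in HKO.

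Among the other genes with high ratios, the clock genes Ciart and Per1 were 13.4-fold (10.5 to 17.3) and 8.75-fold (7.83 to 9.82) higher in HKO. Noct, which encodes the rhythmic phosphatase nocturnin, was 8.27-fold higher, and Zbtb16, a zinc finger transcription factor gene, was 8.88-fold higher, at 1659 against 187 CPM. Selenbp2, a selenium-binding protein gene, was at 741 CPM in HKO and 55.0 CPM in WT. Mfsd2a, a lysophospholipid transporter gene, was 9.22-fold higher, Cyp4a10, a fatty acid hydroxylase gene, 10.1-fold higher, Pcdh11x, a protocadherin gene, 13.8-fold higher, and AA986860 8.42-fold higher. On the low side, Gbp6 was 23.2-fold lower in HKO (17.9 to 30.4), Cxcl10 23.3-fold lower (17.1 to 32.5), Igtp 13.2-fold lower and Cd274 13.0-fold lower. Scd1, a desaturase of fatty acid synthesis, was at 6.53 CPM in HKO and 99.8 CPM in WT. Nr0b2, a repressor of bile acid synthesis, was 13.9-fold lower, Cyp26a1, which breaks down retinoic acid, 16.4-fold lower, and Serpina6, the corticosteroid-binding globulin gene, 13.4-fold lower. Mup11 and Mup7, of the major urinary protein family, were 15.4-fold and 16.0-fold lower, and reads may be shared among the near-identical copies of that family and of the Gbp family. In GRCm38, Cux2 (ENSMUSG00000042589) lies on chromosome 5, 121856366 to 122050102, Lepr (ENSMUSG00000057722) on chromosome 4, 101717404 to 101815352, Lpin1 (ENSMUSG00000020593) on chromosome 12, 16535669 to 16610966, Iigp1 (ENSMUSG00000054072) on chromosome 18, 60376027 to 60392634 and Scd1 (ENSMUSG00000037071) on chromosome 19, 44394455 to 44407879.

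Of 8413 genes with a mean of at least 10 CPM, 250 had a log2 ratio of at least 1 and 369 of at most -1. These are counts by size and not by test. The median log2 ratio of all genes was 0.16, and the higher genes were 40.4% of those past the size. Median ratio size factors shifted every log2 ratio by -0.14 and gave 174 higher and 498 lower genes (25.9% higher), and TMM factors shifted them by -0.12 and gave 190 and 477 (28.5%). A floor of 1 CPM gave 430 higher and 582 lower genes and a floor of 50 CPM 125 and 174. In endothelial-like nuclei Lpin1 was at 458 CPM in HKO and 26.6 CPM in WT and Iigp1 at 149 and 1869 CPM, much the same ratios. Cux2, at 77.8 and 16.6 CPM, and Lepr, at 42.9 and 11.0 CPM, had smaller ratios there, with log2 values of 2.20 and 1.92 against 4.82 and 4.19 in hepatocyte-like nuclei. Across genes, the log2 ratios in hepatocyte-like nuclei correlated with those in endothelial-like nuclei at r = 0.970 over 3817 genes, in macrophage-like nuclei at 0.955 over 3890 and in stellate-like nuclei at 0.938 over 3758, where genes are not independent replicates.

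**Figure D2:**
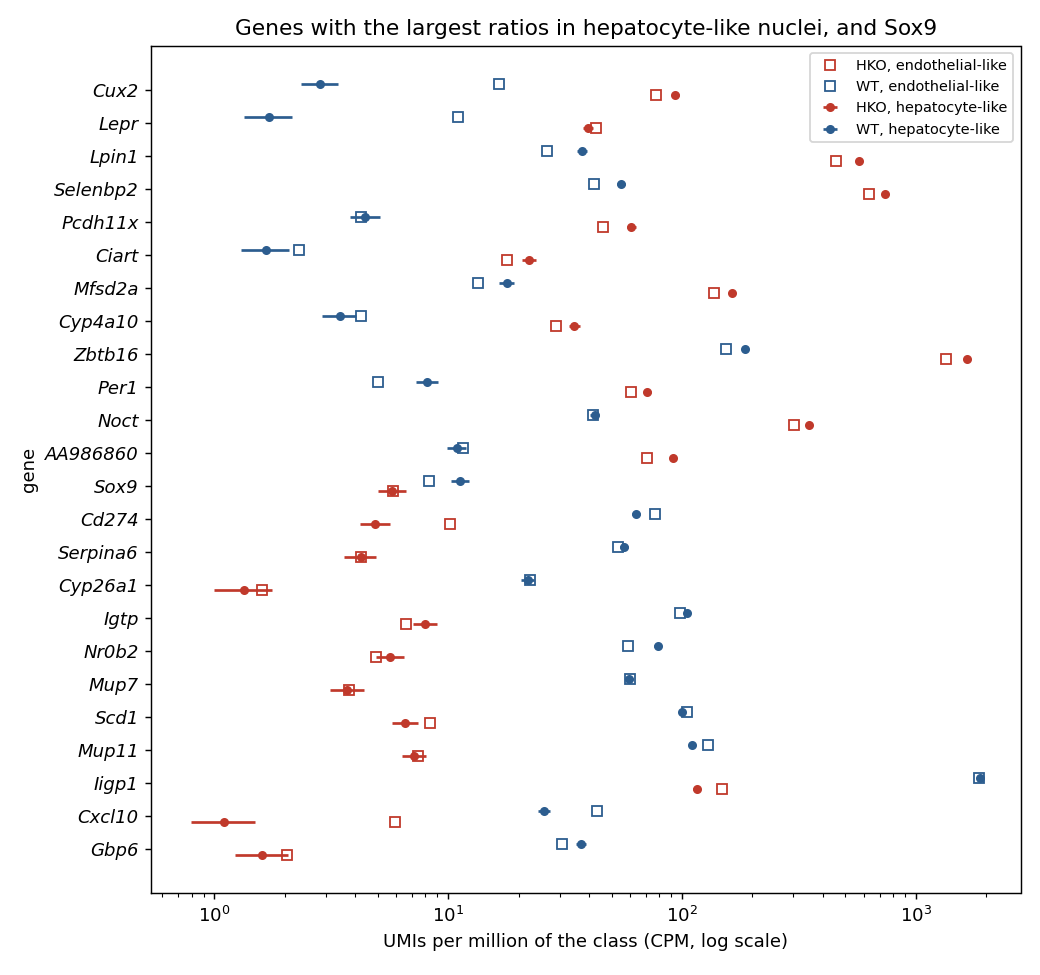
Class-level CPM (log axis) for genes among the 12 highest and the 12 lowest ratios in hepatocyte-like nuclei, and Sox9, in HKO and WT, with exact Poisson 95% intervals as bars and endothelial-like levels as open squares. Zbtb16 stood at 1659 CPM in HKO and 187 CPM in WT and Iigp1 at 115 and 1889 CPM, and endothelial-like values lay near the hepatocyte-like ones for most genes.

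Genes of lipid synthesis were lower in HKO as a group. Of the 25 genes of cholesterol synthesis, 14 had a log2 ratio of at most -1, 11 lay in between and none was at or above 1, with a median of -1.12 (random lists -0.02 to 0.31). Insig1, which restrains sterol synthesis, was 4.88-fold lower in HKO (4.60 to 5.17), Sc5d, a desaturase of the pathway, 4.35-fold lower and Idi1, the isopentenyl diphosphate isomerase gene, 3.41-fold lower. Of 22 measured genes of fatty acid synthesis, 6 were lower, 15 in between and 1 higher, with a median of -0.44 (random lists -0.01 to 0.32). Fasn, the fatty acid synthase gene, was 2.35-fold lower and Aacs 2.56-fold lower, while Lpin1 was the higher member. Each of these medians lay below all 10000 random lists. Low percentiles were not particular to lipid synthesis or to the secreted and cell cycle groups below. Of the 23 scored lists, 13 lay below the random lists and 3 above. Random lists were drawn gene by gene, so they do not reproduce any shared regulation within a list.

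Transcripts of secreted liver proteins were lower in HKO too. Of 27 measured acute phase genes, 12 were lower, 13 in between and 2 higher, with a median of -0.94 (random lists -0.13 to 0.33). Saa2 and Saa1, serum amyloid genes with near-identical copies, were 7.79-fold and 5.15-fold lower in HKO, Orm2 5.92-fold lower and Apcs, the serum amyloid P gene, 5.23-fold lower. Of 23 lipoprotein genes, 9 were lower, 13 in between and 1 higher, with a median of -0.68 (random lists -0.07 to 0.33). The apolipoprotein genes Apoc1, Apoe and Apoa2 were 4.86-fold, 4.08-fold and 3.84-fold lower, and Angptl4, an inhibitor of lipoprotein lipase, was 7.47-fold higher, at 60.7 against 8.13 CPM. Both medians lay below all 10000 random lists. Against random lists matched also on the mitochondrial gradient among WT nuclei, the acute phase median was no longer below, at percentile 9.26 (random lists -1.07 to -0.27). The lipoprotein median was at percentile 1.31, just under its random lists (-0.64 to 0.13). The higher mitochondrial share in WT, 0.265% against 0.0745%, went with the higher level of these abundant transcripts.

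Cell cycle genes were lower in HKO. Of 19 measured genes of G2 and mitosis, 11 had a log2 ratio of at most -1 and 8 lay in between, with a median of -1.01 (random lists -0.10 to 0.30), and of 28 genes of S phase and DNA replication 5 were lower and 23 in between, with a median of -0.66 (random lists -0.04 to 0.28). Top2a, the topoisomerase of dividing cells, was at 35.1 CPM in HKO and 89.9 CPM in WT, the spindle genes Ttk and Aspm were 2.78-fold and 2.67-fold lower, with Cenpf at 7.85 against 19.6 CPM, and the replication genes Brip1, Dtl, Pole and Rfc3 were 2.48-fold, 2.39-fold, 2.31-fold and 2.16-fold lower. Summed over the list, G2 and mitosis transcripts were at 390.4 CPM (384 to 397) in HKO and 798 CPM (790.0 to 807) in WT hepatocyte-like nuclei. Of 17 growth factor and immediate early genes, 4 were lower and 13 in between, with a median of -0.40 (random lists -0.13 to 0.33). Igfbp1 was 5.02-fold lower, the immediate early genes Egr1 and Ier2 3.59-fold and 2.14-fold lower, and Socs3, which restrains cytokine signalling, 2.62-fold lower. At a floor of 50 CPM this list was no longer below the random lists and that of G2 and mitosis had too few members. Of 10 p53 targets and cell cycle inhibitors, 2 were lower, Btg2 by 2.90-fold and Gdf15 by 2.55-fold, and 8 in between, with a median of 0.03 (random lists -0.14 to 0.38).

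Per nucleus, the comparison asked how many hepatocyte-like nuclei carried cell cycle transcripts. After thinning to 2000 UMIs, at least 3 UMIs of the G2 and mitosis list were found in 511 of 7685 HKO nuclei (6.65%, 6.10 to 7.23) and 1481 of 9340 WT nuclei (15.9%, 15.1 to 16.6), with 995 and 97 shallower nuclei left out. Unthinned, the shares were 12.5% and 30.4%. Endothelial-like nuclei gave 8.97% and 19.7%, macrophage-like nuclei 27.4% and 36.1%, stellate-like nuclei 20.7% and 25.0% and T/NK-like nuclei 9.35% and 16.2%. For S phase the hepatocyte-like shares were 23.6% (22.6 to 24.5) and 41.2% (40.2 to 42.2), unthinned 52.0% and 70.7%, against 27.5% and 42.6% in endothelial-like, 43.4% and 55.9% in macrophage-like, 36.3% and 40.3% in stellate-like and 18.7% and 35.9% in T/NK-like nuclei. The hepatocyte-like shares were no higher than the endothelial-like ones in either library. Endothelial-like nuclei held hepatocyte RNA too, so this comparison did not separate background from dividing hepatocytes. Cycling genes led the hepatocyte-like cluster 12, with 525 HKO nuclei, and cluster 9, with 966 WT and 3 HKO nuclei. The macrophage-like shares were above the hepatocyte-like and endothelial-like ones in each library. The size of a share depends on the rule, since 2 UMIs in place of 3 gave 12.3% and 28.1% for G2 and mitosis and thinning to 1000 UMIs 3.84% and 7.92%, with WT the higher each time.

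**Figure D3:**
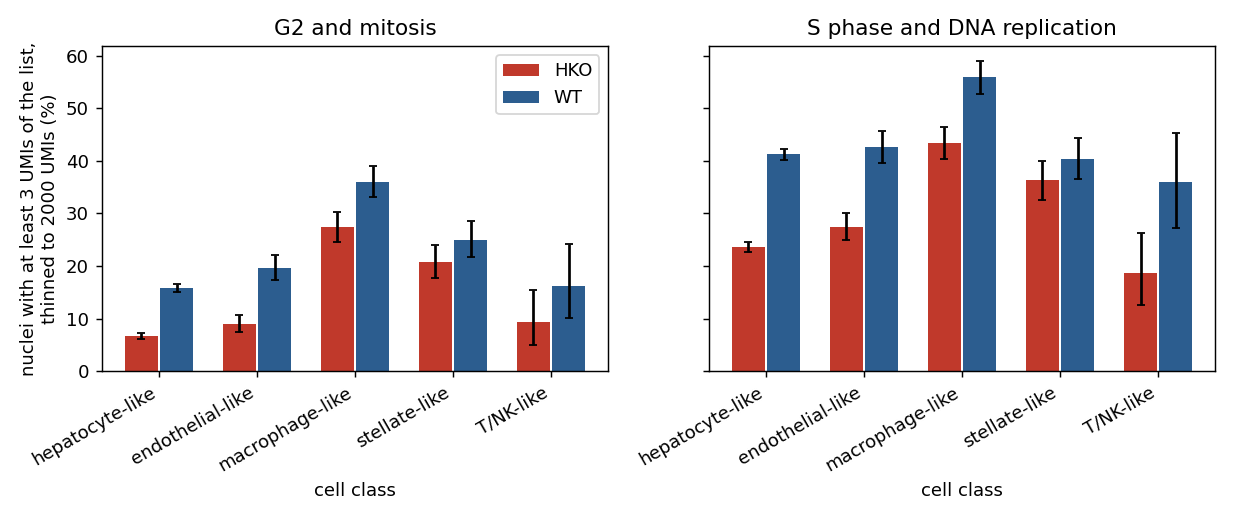
Share of nuclei (percent, y axis) with at least 3 UMIs of the G2 and mitosis list (left) or the S phase and DNA replication list (right) after thinning to 2000 UMIs, by cell class (x axis), in HKO and WT, 1 library each, with exact binomial 95% intervals as bars. For G2 and mitosis, hepatocyte-like nuclei stood at 6.65% in HKO and 15.9% in WT and endothelial-like nuclei at 8.97% and 19.7%.

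Clock genes differed in both directions with a higher median in HKO, and the medians of amino acid and fatty acid use genes were slightly above random lists. Of 17 measured clock genes, 8 had a log2 ratio of at least 1, 3 of at most -1 and 6 lay in between, with a median of 0.84 (random lists -0.06 to 0.35), above all 10000 random lists. Arntl, Nfil3 and Nr1d1 were the lower ones, at log2 ratios of -1.47, -1.17 and -1.03 (chosen after their values were seen). Besides Ciart and Per1, Per2 was 4.70-fold higher in HKO (4.37 to 5.05). Of 33 genes of the urea cycle and amino acid breakdown, 6 were higher, 1 lower and 26 in between, with a median of 0.33 (random lists -0.03 to 0.31). Bhmt, the betaine homocysteine methyltransferase gene, was 4.07-fold higher, Sds, the serine dehydratase gene, 3.74-fold higher and Asl, the argininosuccinate lyase gene, 2.92-fold higher, while Hal, the histidine ammonia lyase gene, was 4.62-fold lower. Of 32 genes of fatty acid oxidation and ketogenesis, 3 were higher and 29 in between, with a median of 0.31 (random lists 0.02 to 0.30). Cyp4a10 stood at 34.6 against 3.43 CPM, Pex11a, a peroxisome gene, was 3.03-fold higher, Crat 2.30-fold higher and Acadm, the medium-chain acyl-CoA dehydrogenase gene, 1.90-fold higher. Weighting every nucleus equally left 1 list above the random lists, the circadian one, and the lists of amino acid breakdown and fatty acid oxidation were no longer above. The first of these also fell within the random lists with the unnamed cluster counted as hepatocyte-like, and the second at a floor of 50 CPM.

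Zonation, drug metabolism and male-biased genes had lower medians in HKO. This was not particular to them, since 13 of the 23 scored lists lay below the random lists. Matching on the mitochondrial gradient was not done for these groups. Of 29 pericentral genes, 7 were lower, 3 higher and 19 in between, with a median of -0.41 (random lists 0.00 to 0.32). Cyp1a2 and Cyp2e1, cytochrome P450 genes, and Lect2, a secreted factor gene, were 5.92-fold, 3.10-fold and 3.44-fold lower, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 4.11-fold higher. Of 30 periportal genes, 9 were lower, 4 higher and 17 in between, with a median of -0.20 (random lists -0.01 to 0.31). Hsd17b6 and Trf, the transferrin gene, were 7.41-fold and 4.80-fold lower. Of 23 genes of cytochrome P450 drug metabolism, 5 were lower, 4 higher and 14 in between, with a median of -0.39 (random lists -0.04 to 0.34). Ces2a, a carboxylesterase gene, and Cyp2c44 were 4.14-fold and 2.73-fold lower and Sult1a1, a sulfotransferase gene, 3.56-fold higher. Of 14 male-biased genes, 4 were lower and 10 in between, with a median of -0.33 (random lists -0.22 to 0.36), among them Hsd3b5, 9.60-fold lower, Nudt7, 4.88-fold lower, and the paralogous Serpina1e and Mup3, 4.99-fold and 2.71-fold lower. This list was no longer below the random lists at a floor of 50 CPM. Only 4 of 23 female-biased genes were measured, too few for a percentile, of which Cux2, Cyp4a10 and Fmo2 were higher, Fmo2 by 7.73-fold, and Abcd2 had a log2 ratio of 0.00. Cyp2a4, a female-biased gene under the floor, went the other way, at 0.0525 CPM in HKO and 11.6 CPM in WT (chosen after its values were seen).

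Small shifts were seen in further groups. Of 18 oxidative stress genes, 2 were lower and 16 in between, with a median of -0.10 (random lists -0.04 to 0.35). Osgin1 and Gpx1, a glutathione peroxidase gene, were 5.64-fold and 2.23-fold lower, while Ugdh was 1.96-fold higher and Gclc, of glutathione synthesis, 1.81-fold lower. Of 23 genes of glucose metabolism, 4 were higher, 2 lower and 17 in between, with a median of -0.02 (random lists -0.02 to 0.34) at percentile 2.4. The sign of this median turned in 3 alternatives, so no direction is read. In those 3, at floors of 1 and 50 CPM and in nuclei of at least 5000 UMIs, the list was no longer below. Slc37a4, the glucose-6-phosphate transporter gene, Foxo1 and Slc2a2, the liver glucose transporter gene, were 3.03-fold, 2.82-fold and 2.59-fold higher and Ppp1r3c, of glycogen synthesis, 3.75-fold lower.

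The remaining groups with a percentile lay within the central 95% of random lists, though the bile acid list was below them at a floor of 1 CPM. The medians of the lipid droplet, bile acid, Notch and p53 lists crossed 0 under other settings, so no direction is read for them. Of 14 lipid droplet genes, 4 were higher, 1 lower and 9 in between, with a median of 0.28 (random lists -0.13 to 0.34). Plin5 and Cidec, lipid droplet coat genes, and Mgll, a lipase gene, were 3.09-fold, 2.90-fold and 2.70-fold higher and Fabp1, the liver fatty acid binding protein gene, 6.88-fold lower. Of 22 bile acid genes, 3 were higher, 3 lower and 16 in between, with a median of 0.02 (random lists -0.06 to 0.34). Slco1a4, an uptake transporter gene, was 3.60-fold higher and Abcb11, the bile salt export pump gene, 2.79-fold lower. Of 18 endoplasmic reticulum stress genes, 3 were higher and 15 in between, with a median of 0.17 (random lists -0.03 to 0.35), and Herpud1, Ddit3 and Creld2 were 3.35-fold, 2.21-fold and 2.05-fold higher. Of 23 hepatocyte transcription factors, 3 were higher, 2 lower and 18 in between, with a median of 0.18 (random lists -0.06 to 0.33). Nr1i3, the receptor CAR, was 2.16-fold higher and Onecut1 2.07-fold lower. Of 7 YAP and TEAD targets, 2 were lower, Dlc1 by 3.22-fold and Nuak2 by 2.59-fold, with a median of 0.23 (random lists -0.27 to 0.44). Of 18 Notch pathway genes 7 were measured and lay in between, with a median of 0.14 (random lists -0.26 to 0.45) and Hes1, a Notch target, at 9.03 against 17.1 CPM. Notch3, a receptor gene whose mean was under the floor, was at 11.4 CPM in HKO and 0.841 CPM in WT (chosen after its values were seen). Only 4 ductal and progenitor genes were measured, of which 1, Onecut1, was lower and 3, among them Pkhd1 at a log2 ratio of -0.49, lay in between.

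**Figure D4:**
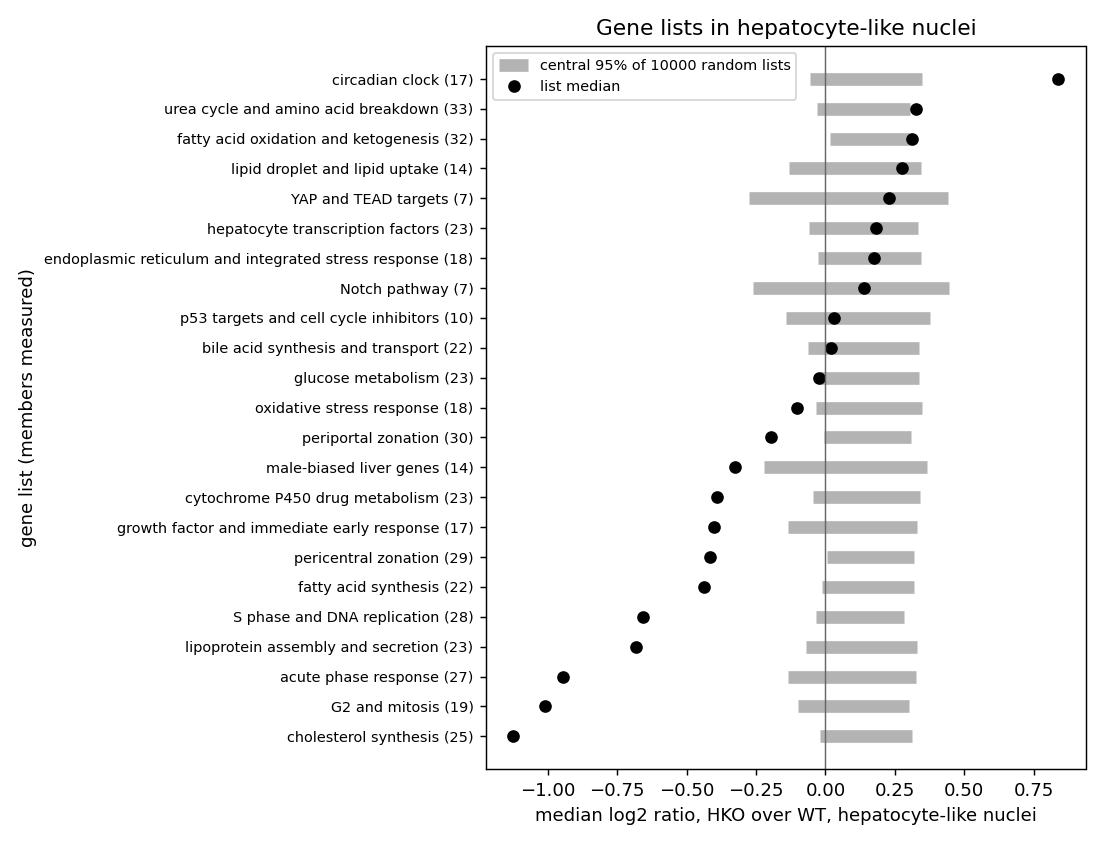
Median log2 ratio of HKO over WT (x axis) of each gene list (y axis, with the number of members measured) in hepatocyte-like nuclei, with grey bars for the central 95% of 10000 random lists matched on mean expression. Circadian clock genes stood above their bar at 0.84, and cholesterol synthesis genes below theirs at -1.12.

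Other cell classes were compared for genes at least as high there as in hepatocyte-like nuclei, whose levels are given beside them because hepatocyte RNA was in every class. In macrophage-like nuclei, 20 of 1624 genes were higher and 29 lower in HKO. Rassf4, Cd55, a complement regulator gene, and Csf3r, the G-CSF receptor gene, were higher and far above the hepatocyte-like level. Csf3r was also among the neutrophil markers, and no cluster could take that name, so neutrophils among these nuclei were not excluded. Rassf4 was at 149 CPM (140.1 to 158) in HKO and 40.6 CPM (35.6 to 46.0) in WT, against 9.21 and 4.39 CPM in hepatocyte-like nuclei, and Csf3r at 77.1 and 29.9 CPM, against 3.83 and 1.85 CPM. St3gal5 and Hspa4l also had high ratios, but Hspa4l lay near its hepatocyte-like level in both libraries and St3gal5 in HKO only, at 864 against 846 CPM in HKO and 285 against 124 CPM in WT. Among the lowest were Irf1 and the paralogous Gbp4, Gbp5 and Gbp7, all interferon-inducible. Irf1 lay nearer its hepatocyte-like level, at 39.3 against 30.9 CPM in HKO and 212 against 147 CPM in WT. Gbp7 was at 23.5 against 11.5 CPM in HKO and 110 against 70.6 CPM in WT. Hepatocyte RNA may therefore enter the ratios of Irf1 and Gbp7. Gbp5 was at 9.85 CPM (7.68 to 12.4) in HKO and 96.0 CPM (88.3 to 104) in WT, against 1.23 and 5.44 CPM in hepatocyte-like nuclei. Only 4 members of the macrophage inflammation list were measured, and none was past the size in either direction. They were Marco, Clec4f, Timd4 and Mrc1. Cytokine and chemokine genes of the list, such as Il1b, Tnf and Ccl2, were not measured, so inflammation was not assessed. Marco, a scavenger receptor gene of resident macrophages, was at 556 CPM in HKO and 282 CPM in WT, Clec4f at 92.5 and 141, Timd4 at 285 and 221 and Mrc1 at 137 and 147.

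In endothelial-like nuclei, 9 of 1375 genes were higher and 55 lower in HKO. Mlxip, a glucose-responsive transcription factor gene, was at 131 CPM (124 to 139) in HKO and 53.7 CPM (47.6 to 60.4) in WT, against 42.2 and 27.2 CPM in hepatocyte-like nuclei, and Serinc3 at 161 and 67.8 CPM, against 88.6 and 45.1 CPM. P4ha1, Tmtc2 and Stip1 lay near their hepatocyte-like levels with much the same ratio, and the lowest ratios were those of the hepatocyte transcripts Mup11, Scd1, Serpina1d, Orm2 and Apcs. None of 12 angiocrine and regeneration genes was past the size, with a median log2 ratio of 0.21 at percentile 53.9, and Rspo3, a Wnt enhancer gene, was at 56.5 CPM in HKO and 87.4 CPM in WT and Bmp6 at 101 and 66.2 CPM. In stellate-like nuclei, 13 of 1357 genes were higher and 62 lower. Il34, a macrophage growth factor gene, was at 184 CPM (171 to 197) in HKO and 79.96 CPM (69.9 to 91.0) in WT, against 1.60 and 0.911 CPM in hepatocyte-like nuclei, and Acer2, a ceramidase gene, at 112 and 49.2 CPM, against 21.0 and 10.1 CPM. Tns1 lay near its hepatocyte-like level, P4ha1 and Pcdh11x had high ratios in both classes, and the lowest ratios were those of Scd1, Serpina1d, Trf, Igtp and Gbp4. None of 13 stellate activation and matrix genes was past the size, with a median of 0.03 at percentile 15.8. The collagen genes Col14a1 and Col3a1 were at 227 and 81.9 CPM in HKO and 372 and 119 CPM in WT. Col4a1 and Col4a2 went the other way, at 142 and 101 CPM in HKO and 106 and 82.4 CPM in WT. In T/NK-like nuclei, 10 of 1195 genes were higher and 55 lower. Ccnd3, a cyclin gene, was at 562 CPM (517 to 609.7) in HKO and 169.8 CPM (137 to 209) in WT, against 222 and 71.4 CPM in hepatocyte-like nuclei. Lpin1 and P4ha1, also high, and Scd1, Orm2, Cyp1a2 and Apoe, among the lowest, are read as hepatocyte RNA, and Plekhg1, also low, is an endothelial marker. These counts still hold hepatocyte transcripts slightly higher in another class, and they rest on the floor, since 100 CPM gave 5 higher and 29 lower genes in endothelial-like nuclei and keeping all genes 106 and 191.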

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

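Alternatives restricted to barcodes of at least 2000 UMIs, without the highest doublet scores, in nuclei of at least 5000 UMIs, or counting the unnamed cluster as hepatocyte-like were chosen after seeing the data. No paired analysis was possible because each group has 1 library and no result comes from a test. Averaging the ratio within each hepatocyte-like cluster could not be computed because each cluster holds nuclei of 1 library or, in cluster 9, only 3 of HKO. Of the 93 named genes past a log2 ratio of 1 in size, all kept their sign in every alternative run and 87 to 93 stayed past it. These genes were picked for their ratios in the same libraries, and floors do not change a gene's ratio. This stability therefore says nothing about other livers. Over all alternatives, 987 values of named genes were labelled unchanged and 321 moved, among them 71 under median ratio size factors and 67 under TMM. For list medians, 307 were labelled unchanged, 8 moved and 3 medians of called lists changed sign. Lists that were not called also crossed 0, with lowest medians of -0.12 for bile acid, -0.11 for p53, -0.0022 for Notch and -0.0077 for lipid droplet genes. The glucose metabolism median turned to 0.0253 at resolution 1, 0.0304 with the unnamed cluster counted and 0.0037 after thinning; the cause was not tested. A gene minimum of 200 left every value as it was, because no barcode has fewer than 500 genes.

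The hepatocyte-like share was 61.4% in HKO with at least 1000 genes per nucleus, 69.5% with at least 2000 UMIs, and 62.0% in HKO and 66.8% in WT without the highest doublet scores. At resolution 1 it was 36.6% in HKO and 66.2% in WT, and the cell cycle shares were 9.42% in HKO for G2 and mitosis and 26.5% in HKO and 40.02% in WT for S phase. Counting the unnamed cluster gave a WT share of 78.8% and a WT S phase share of 40.1%. Equal weights per nucleus left 1 list above the random lists. At resolution 1 a cluster of 3215 HKO nuclei led by haemoglobin genes was left unnamed, which lowers the HKO share by construction, and counting the unnamed cluster raises the WT share by construction. The cause of the other moves was not tested. At a floor of 50 CPM the G2 and mitosis list had too few members to score, and the growth factor, male-biased and glucose metabolism lists were no longer below. At a floor of 1 CPM the bile acid list was below and the glucose metabolism list no longer was.

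Floors change the counts by construction, since other genes enter. A floor of 1 CPM gave 430 higher and 582 lower genes in hepatocyte-like nuclei and one of 50 CPM gave 125 and 174. In the other classes a floor of 100 CPM gave 5 and 29 in endothelial-like, 7 and 10 in macrophage-like, 8 and 28 in stellate-like and 3 and 27 in T/NK-like nuclei, and keeping hepatocyte-high genes gave 106 and 191, 97 and 170, 100 and 191, and 163 and 194. The cell cycle shares follow their rule in the same way. Unthinned they were 12.5% in HKO and 30.4% in WT for G2 and mitosis and 52.0% and 70.7% for S phase, with at least 2 UMIs 12.3%, 28.1%, 43.2% and 62.4%, and thinned to 1000 UMIs 3.84%, 7.92%, 9.63% and 17.9%. WT was the higher library in each.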

Other observations

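The interferon, clock and glucocorticoid lists below and the tests on them, on free RNA and on doublets were chosen after the results were seen, while the tests on cytoplasmic RNA were fixed before their results. Interferon-inducible genes had negative median ratios in each class compared. Of 34 measured in hepatocyte-like nuclei, 18 had a log2 ratio of at most -1, none of at least 1, and 32 were negative, with a median of -1.19 (random lists 0.01 to 0.29). Irgm2, an immunity-related GTPase gene, was at 44.5 CPM in HKO and 208 CPM in WT, Psmb9, an immunoproteasome gene, at 9.34 and 48.3 CPM, and Tapbp, of antigen presentation, at 22.3 and 61.8 CPM. Stat2 and Usp18, also inducible by interferon, were at log2 ratios of -0.01 and 0.14. The median was -1.09 in macrophage-like nuclei (24 of 44 at most -1), -1.04 in stellate-like (24 of 47), -0.76 in endothelial-like (18 of 41, with 1 at least 1) and -0.58 in T/NK-like nuclei (17 of 39), where free RNA is included and no random lists were drawn.

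The first pattern weighed is that gene ratios were alike in hepatocyte-like and other classes. Barcodes that pair a hepatocyte with another nucleus would hold at least the UMIs of a hepatocyte. The median UMIs of endothelial-like nuclei were at most 0.857 of the hepatocyte-like ones. Among barcodes of at least 2000 UMIs, however, the mainly HKO endothelial-like cluster had a median of 3838 UMIs. The HKO hepatocyte-like clusters had 3812.5 to 4215.5 there, so the depths do not decide on pairs. Hepatocyte markers at 85.5% or more of their hepatocyte-like level in endothelial-like nuclei, with endothelial markers in hepatocyte-like nuclei at 4.47% and 5.50%, are consistent with free hepatocyte RNA in every droplet. Free RNA carries the livers' hepatocyte transcripts, so it blurs which class a ratio belongs to, and whether it also moves ratios between the libraries was not tested. The genotype stays open and was not tested, since it is confounded with the library.

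The second pattern is that clock genes differed. Genes that peak late in the light phase, such as Per1, Per2 and Ciart, had a median log2 ratio 2.04 above that of genes that peak near its start, which is consistent with livers collected at different times of day, as a hypothesis. The early set has only 4 measured members, Arntl at -1.47, Nfil3 at -1.17, Clock at -0.21 and Cry1, which goes the other way, at 0.84. Nr1d1, a daytime gene in neither set, was at -1.03, while Nr1d2, placed in the late set, was at 0.36. Both sets were written after the results were seen and no unseen members were scored apart. The gap therefore describes the pattern and does not test it. A different glucocorticoid level remains open, since the median of 16 glucocorticoid-induced genes outside the clock list lay at percentile 84.9 of random lists, with 5 of them at least 1, such as Fkbp5 at 1236 against 166 CPM, none at most -1 and 6 negative, which decides nothing (the reading of this value was set after it was seen). The genotype is likewise open and untested.

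The third pattern is that groups of secreted, lipid and cell cycle genes were lower in HKO while WT nuclei had more mitochondrial RNA. Random lists were matched also on how genes differ between WT nuclei of high and low mitochondrial share. Against them, cholesterol synthesis and G2 and mitosis stayed below all lists, at percentiles of 0.0 and 0.0. For these groups, the part of cytoplasmic RNA that this gradient captures did not account for the lower medians. Lipoprotein genes were at percentile 1.31, with a median of -0.68 just under the random lists (-0.64 to 0.13). Across genes the matched difference correlated with the library ratio at only -0.18. The matching may thus be incomplete for every group. Cytoplasmic RNA stays open for lipoprotein genes and is not excluded for cholesterol synthesis or G2 and mitosis genes. Acute phase genes moved to percentile 9.26, so more cytoplasmic RNA in the WT library could account for much of their lower median. For interferon genes, the 19 measured members not yet seen when the list was written had a median of -0.69 at percentile 0.0, with 4 at most -1, among them Irgm2, Psmb9 and Tapbp, and 15 in between, which fits an interferon response in the WT library, as a hypothesis. An infection or stimulus in 1 animal, the genotype and the library were not tested apart.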
